A study of Mus musculus with 8 samples.

How the data were processed

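RNA from bladder tumours of C57BL/6 mice treated with BBN was sequenced in 8 libraries, 4 from wild-type and 4 from Agl knockout mice. The deposited count table gives raw read counts for 35275 Ensembl genes in each library. The submitters' processing notes name CASAVA, Bowtie 0.12.2 and TopHat2 together with the mouse builds mm8 and mm9, per the labels, with no role for any of them, and the counting tool is not given there. The deposited FPKM table covers the same genes, and over 10740 genes with at least 50 reads in every library each FPKM equalled the count times a constant for the gene divided by the library total, to within a relative difference of 9.77e-15. The FPKM values are therefore the same measurement on another scale. Symbols were found for 34490 of the gene IDs in the GENCODE M21 annotation, whose build differs from those in the processing notes, so no positions are given. Reads in genes without a symbol made up 0.0689% to 0.109% of a library and stayed in the totals.

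Totals ran from 15919607 to 23112120 reads per library. Intervals on counts are exact binomial (Clopper-Pearson) at 95% and cover counting error only.

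The libraries of KO replicates 3 and 4 were compared with all other pairs before any group test, through the chi-square per degree of freedom over genes with at least 20 reads and through the Spearman correlation. They were close enough to be counted as 1 sample, and their counts were summed and their FPKM values averaged. The design fixed before the data were examined had all 8 libraries as separate samples, and that fit is given as an added alternative. The comparisons thus rest on 4 WT and 3 KO samples, which can be split into groups of these sizes in 35 ways, and the smallest exact permutation p is 0.0286.

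Genes were kept by the default of edgeR's filterByExpr by group, counts were scaled by TMM, and KO was compared with WT by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are scaled by TMM except in the plot of Agl per library. Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Beside it stood camera with an estimated correlation, fry and an exact permutation test of the list means. The 35 lists were fixed before the data were examined, for glycogen metabolism, hyaluronan and glycine, for other pathways of bladder tumours and for the cell types a bladder can hold, and lists with under 3 tested members were not tested. A list's mean difference is that of its log2 CPM, its median is that of the edgeR log2 fold changes of its members, and members are given by their edgeR log2 fold changes. The similarity of samples was the mean Spearman correlation of log2 CPM within groups minus that between groups.

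The genes named were also chosen by a rule fixed before the data were examined. It takes Agl first, then 10 genes higher and 10 lower in KO by size of change among those passing the adjusted threshold or, where none passed, by the smallest unadjusted p. These need an average log2 CPM of at least 1 and no overlap between the groups, and predicted genes known only by a clone name are passed over. It adds up to 4 members with the smallest p of each list described, the genes Has1, Has2, Has3, Cd44, Hmmr, Shmt1, Shmt2, Xist, Upk2, Krt5, Krt14, Trp63, Mki67, Myh11 and Col1a1 whatever their values, and the members of any count of 5 or fewer.

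The tests were tried on simulated data with the means, library sizes and spread of these samples and 200 changed genes, 50 at each of 4 fold sizes. The edgeR test recovered 2% of genes changed 2-fold, 22% at 4-fold, 52% at 8-fold and 74% at 16-fold, and called 2 of 15359 genes simulated without a change. A list shifted by 1 on the log2 scale was recovered by limma camera with an adjusted p of 6.42e-10, and 0 other lists were called. The simulated genes varied independently, while the estimated correlation in the real lists had a median of 0.441. The simulation therefore cannot say how often camera calls unchanged lists in these samples. The median biological coefficient of variation of the real samples was 0.458.

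Alternatives covered DESeq2 size factors, upper-quartile factors and library totals alone, the DESeq2 1.42.0 Wald test, limma voom with and without sample quality weights, robust edgeR fits, no filter and a filter of 1 CPM in 4 samples, limma on log2(FPKM + 1) and log2(FPKM + 0.1), summing genes that share a symbol, an adjusted threshold of 0.1, a prior count of 0.5, Pearson correlation, the 500 most variable genes and leaving out each replicate in turn. Chosen after the data were examined were the DESeq2 test on the genes kept by filterByExpr without its own filter, the fit with KO replicates 3 and 4 apart, the fits without both of them and without WT replicate 1 and KO replicate 2, and fits with the mean of the Y-linked list or of the smooth muscle list as a covariate.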

Results

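The data are RNA sequencing profiles of bladder tumours from mice that carried or lacked Agl, the gene for the glycogen debranching enzyme. The comparison asks what the loss of this enzyme does to gene expression in tumours brought on by a carcinogen. The C57BL/6 mice had received 0.05% BBN, a nitrosamine that causes bladder tumours, over 12 weeks. There were 4 libraries from wild-type (WT) and 4 from knockout (KO) tumours. Reads counted in genes came to 18438216, 23112120, 18839685 and 16298990 in WT replicates 1 to 4, and to 16371834, 17878599, 15919607 and 19004975 in KO replicates 1 to 4. The libraries of KO replicates 3 and 4 were nearly identical, with a Spearman correlation of 0.997 over 15652 genes against at most 0.964 for the other 27 pairs. They were summed and counted as 1 sample, so that 4 WT samples were compared with 3 KO samples.

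Agl was lower in every KO library than in any WT library. It stood at 41.6 ± 12.9 CPM (SD, n = 4) in WT and at 7.12 ± 6.57 CPM (SD, n = 3) in KO tumours, a log2 fold change of -2.55 (SE 0.63). The exact permutation test on log2(CPM + 1) gave p = 0.0286, two-sided, the smallest that 4 samples against 3 allow, and edgeR's adjusted p over all genes was 0.9998. WT replicates 1 to 4 held 581, 1494, 525 and 790 Agl reads, and KO replicates 1 to 4 held 40, 231, 77 and 81. Relative to the WT mean, Agl was at 5.81% in KO replicate 1, at 35.2% in KO replicate 2 and at 10.4% in the summed KO replicates 3 and 4. The labels do not say which part of the gene was deleted, and reads from outside that part stay in the count.

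**Figure D1:**
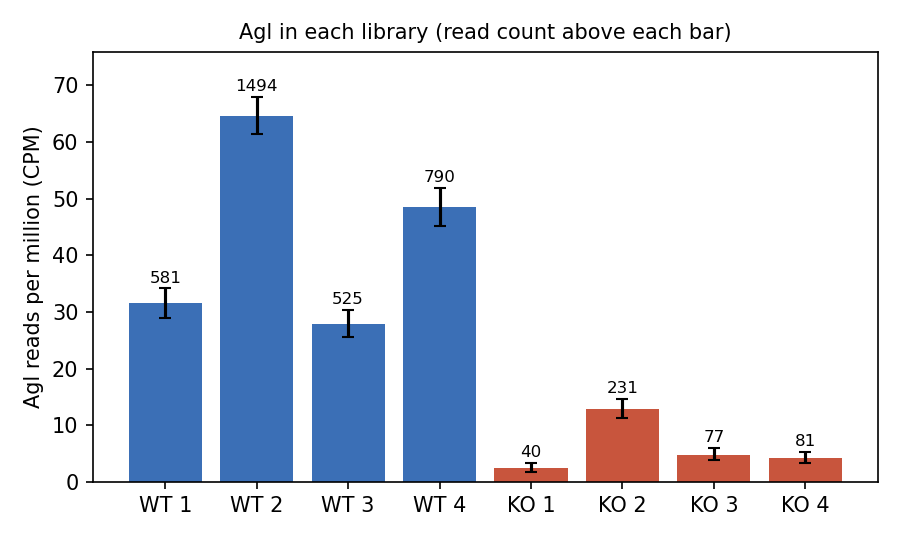
Agl CPM, relative to all reads counted in genes (vertical axis), in each of the 8 libraries, WT in blue and KO in red, with the read count above each bar and exact binomial 95% confidence intervals that cover counting error only. All 4 KO libraries lie below all 4 WT libraries, and KO replicate 2 is the highest KO library with 231 reads.

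Beyond Agl, Cyp2a5, Cyp2b10, Wnt3a and Gdf15 had the largest log2 fold changes among the 10 genes named on the higher side, and Lgi2, Otulinl, C3ar1 and Sox18 followed Agl on the lower side. Cyp2a5 and Cyp2b10, which encode cytochrome P450 enzymes, were at 6.59 ± 3.14 and 9.10 ± 5.47 CPM in KO (SD, n = 3) against 0.806 ± 0.392 and 1.64 ± 0.483 CPM in WT tumours (SD, n = 4). Wnt3a, a secreted Wnt ligand, was at 8.92 ± 2.69 CPM in KO against 2.28 ± 0.733 in WT, and Gdf15, a stress-induced cytokine, at 6.83 ± 3.11 against 1.63 ± 0.319. Thbd, the thrombin receptor of blood vessels, was at 33.4 ± 2.58 CPM in KO against 70.2 ± 16.9 in WT, and Sox18, a transcription factor of endothelial cells, at 8.63 ± 0.782 against 21.4 ± 7.27. Mpeg1, a pore-forming protein of macrophages, was at 47.0 ± 5.68 CPM in KO against 85.6 ± 15.2 in WT.

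In these 20 genes no KO value overlapped a WT value, because the rule that named them required it. The log2 fold changes on the higher side were 3.03 for Cyp2a5, 1.97 for Wnt3a, 2.06 for Gdf15, 2.47 for Cyp2b10, 0.90 for Tbc1d2, 1.44 for Rhpn2, 0.97 for Epb41l4a, 1.03 for Ccdc120, 1.24 for Pim3 (0.79 without KO replicate 2) and 0.94 for Prkx. On the lower side, Thbd was at -1.07, Mpeg1 at -0.86, Sox18 at -1.31, Lgi2 at -2.18, C3ar1 at -1.37, Otulinl at -1.49, Cd34 at -1.18, Rgma at -1.22 and Aplnr at -1.05. Their standard errors lay between 0.21 for Tbc1d2 and 0.64 for Cyp2a5. Cyp2a5 and Cyp2b10 have closely similar neighbours in their gene families, so reads may be split between copies and both values are uncertain.

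None of the 15591 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, where the smallest adjusted p was 0.9998. At an unadjusted p under 0.05 there were 337 genes, 237 of them higher and 100 lower in KO, while chance alone gives 779.6, and this count was 588 without WT replicate 1 and 206 without WT replicate 2. The groups did not overlap in 518 genes, 3.32% of those tested, and chance gives 5.71%. DESeq2 with its own filter tested 24387 genes and called 5, all higher in KO tumours: Cyp2a5, Gsto2, AU018091, Wnt3a and Gdf15. On the genes kept by edgeR's filter, of which it tested 15411, it called 2, Cyp2a5 and Gsto2. Gsto2 overlapped between the groups, with KO values of 3.50, 235 and 16.1 CPM. limma voom called 0 genes with equal sample weights and 0 with estimated ones. In counts simulated at the spread of these samples, the edgeR test recovered 22% of genes changed 4-fold and 74% of those changed 16-fold.

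**Figure D2:**
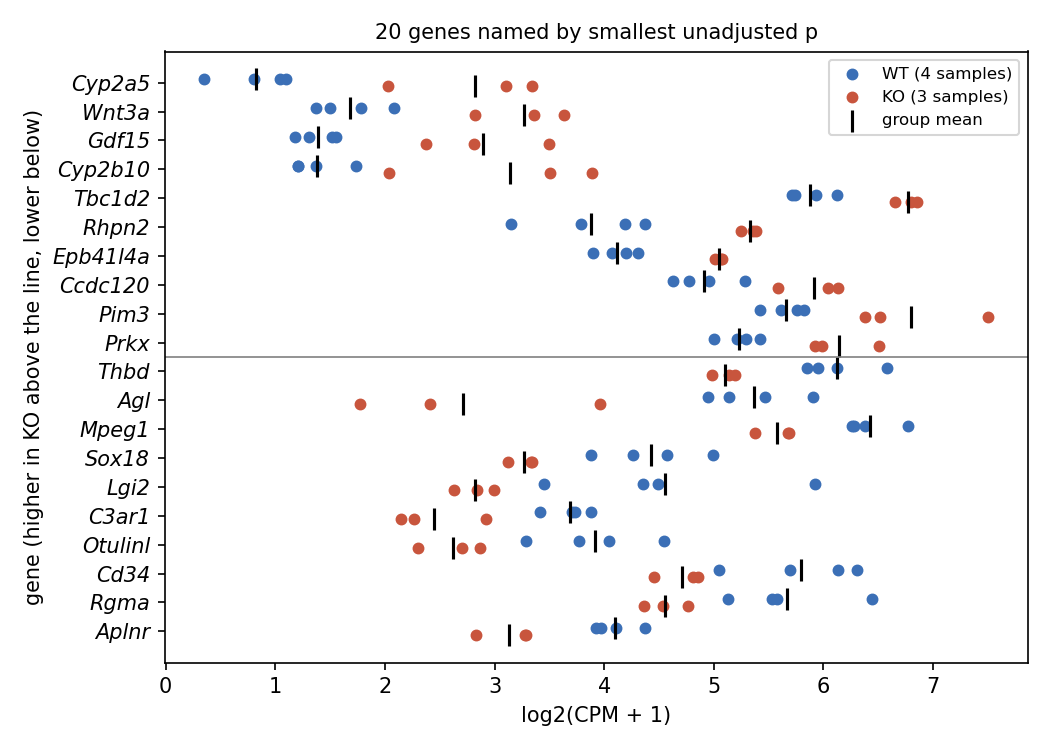
Expression of the 20 genes named for the smallest unadjusted p, as log2(CPM + 1) on the horizontal axis, with 1 point per sample (4 WT in blue, 3 KO in red) and a black bar at each group mean. The KO points lie apart from the WT points in each gene because the rule that named the genes required it, and the Agl points of the KO group span 2.42 to 14.6 CPM.

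Has1, Has2, Has3, Cd44, Hmmr, Shmt1 and Shmt2, genes of the hyaluronan and glycine pathways, overlapped between the groups. Earlier bladder tumour work had linked these pathways to AGL. Cd44, the hyaluronan receptor, was at 487 ± 233 CPM in KO (SD, n = 3) against 300.5 ± 78.1 in WT tumours (SD, n = 4), with a log2 fold change of 0.70, or 0.32 without KO replicate 2. Has2, a hyaluronan synthase, was at 5.15 ± 4.64 CPM in KO against 7.87 ± 6.61 in WT, and Shmt2, which makes glycine from serine in mitochondria, at 89.5 ± 19.4 against 97.1 ± 88.2. The log2 fold changes of Has1, Has3, Hmmr and Shmt1 were -0.12, 0.15, -0.57 and 0.02. With 1 sample left out, Has1 ran from -0.53 to 0.27, Has2 from -1.64 to 0.00, Has3 from -0.23 to 0.42, Hmmr from -0.91 to 0.08, Shmt1 from -0.12 to 0.23 and Shmt2 from -0.36 to 0.75. The hyaluronan list, with 13 tested members, had a mean log2 difference of -0.01 and a median edgeR log2 fold change of 0.15 (limma camera, adjusted p = 0.779, on the higher side), so that its mean differed in sign from its median and test. Members with the smallest p besides Cd44 and Hmmr were the hyaluronidases Hyal1 at 0.38 and Hyal2 at 0.33. Hyal1 was at 0.12 without KO replicates 3 and 4, 0.20 without WT replicate 1 and 0.68 without KO replicate 2. Hyal2 did not overlap between the groups, at 60.7 to 65.8 CPM in KO and 45.9 to 58.8 in WT tumours, and its exact permutation p was 0.0571.

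The serine, glycine and folate list had 9 members above 0 and 8 below, with a mean difference of 0.24 and a limma camera adjusted p of 0.199. It was called without WT replicate 1, with a mean of 0.29 (limma camera adjusted p = 0.0139), and without KO replicates 3 and 4, at 0.47 (0.0051). Both calls used the preset correlation. Camera with an estimated correlation, run with all samples only, gave an adjusted p of 0.990, a value that every list shared after adjustment. Phgdh, the first enzyme of serine synthesis, was at 86.6 ± 36.5 CPM in KO (SD, n = 3) against 44.9 ± 13.4 in WT (SD, n = 4), Mthfd1l had a log2 fold change of 1.13, or 0.26 without KO replicate 2, Gcsh of -0.37, or -0.19 without WT replicate 3, and Mthfd1 of 0.24, or 0.05 without KO replicate 1. In the glycogen list, which leaves out Agl, 16 of 21 members were lower in KO tumours, with a mean difference of -0.20 and a limma camera adjusted p of 0.309. It was called on the lower side without WT replicate 1, with a mean of -0.38 (limma camera adjusted p = 0.0487), and without WT replicate 3, at -0.34 (0.0102). These calls also used the preset correlation, and with an estimated one and all samples the camera adjusted p was 0.990. The mean of the glycogen list turned to 0.03 without WT replicate 2. Ppp1r3b, which targets a phosphatase to glycogen, was at 9.85 ± 4.49 CPM in KO against 20.4 ± 7.91 in WT, Ppp1r3c had a log2 fold change of -1.76, the glycogen-binding protein gene Stbd1 of -0.65 and the glycogen phosphorylase gene Pygl of -0.42. Without WT replicate 2, Ppp1r3c was at -1.13 and Stbd1 at -0.38, and without KO replicate 2 Pygl was at -0.71.

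The basal and luminal urothelium lists were higher in the KO tumours under limma camera with a preset correlation of 0.01, and both calls were lost with an estimated correlation (adjusted p = 0.990). The basal urothelium list had a mean log2 difference of 0.58 (SE 0.45, limma camera adjusted p = 0.000144, and adjusted p = 0.990 with an estimated correlation), and 10 of its 17 members lay above 0. Its median member was at 0.33, and Krt14 (-0.04), Trp63 (-0.14) and Dsc3 (-1.38) were among the 7 below 0. Itgb4, Col17a1, Lamc2 and Lamb3, which anchor basal cells to the basement membrane, had log2 fold changes of 1.27, 1.15, 2.16 and 1.42. Lamc2 and Lamb3 rested on KO replicate 2, without which they were at 0.63 and 0.43. Itgb4 was at 1034 ± 286 CPM in KO (SD, n = 3) against 428 ± 73.8 in WT (SD, n = 4). The luminal urothelium list had a mean difference of 0.61 (SE 0.95, limma camera adjusted p = 0.00296, and adjusted p = 0.990 with an estimated correlation), with Elf3 at 0.85, the tight junction genes Cldn4 at 1.34 and Cldn8 at -1.52, and Erbb3 at 0.46. Of its 23 members 15 lay above 0, with a median of 0.23. The uroplakin genes Upk1a, Upk1b, Upk2, Upk3a and Upk3b were at 0.23, 0.01, -0.20, -0.53 and -0.26. The basal call with the preset correlation held without any 1 sample, but its mean was 0.92 without WT replicate 1, 0.37 without WT replicate 4 and 0.35 without KO replicate 2. Single libraries set the luminal difference, whose mean turned to -0.03 without WT replicate 1 (limma camera adjusted p = 0.170) and was 0.08 without KO replicate 1 (0.573). It was 0.97 without WT replicate 2, 1.03 without WT replicate 4 and 1.14 without KO replicate 2, where Cldn4 was at 0.81, Cldn8 at -1.01 and Erbb3 at 0.69. Cldn8 was at -2.69 without KO replicate 1, and Erbb3 at 0.27 without KO replicates 3 and 4.

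Immediate early genes, inflammatory cytokines, p53 targets and lipid synthesis were also called on the higher side, each with an adjusted p of 0.990 with an estimated correlation. The immediate early list had a mean difference of 0.54 (SE 0.41, limma camera adjusted p = 0.000144, and adjusted p = 0.990 with an estimated correlation). Of its 17 members 15 lay above 0, and Zfp36, Dusp1, Ier3 and Egr1 were at 1.20, 1.15, 1.07 and 1.12. The inflammatory cytokine list had a mean difference of 0.76 (SE 0.83, limma camera adjusted p = 0.00296, and adjusted p = 0.990 with an estimated correlation), with Lcn2 at 2.10, Ptgs2 at 1.97, Il11 at 2.63 and Lif at 1.72. Targets of p53 had a mean difference of 0.35 (SE 0.20, limma camera adjusted p = 0.00417, and adjusted p = 0.990 with an estimated correlation), with Gdf15 at 2.06, Sesn2 at 1.08, Zmat3 at 0.66 and Cdkn1a at 0.93. Fatty acid and cholesterol synthesis had a mean difference of 0.22 (SE 0.29, limma camera adjusted p = 0.0124, and adjusted p = 0.990 with an estimated correlation), with Ldlr, the receptor for low-density lipoprotein, at 221 ± 40.7 CPM in KO (SD, n = 3) against 116 ± 13.9 in WT (SD, n = 4). Dhcr24, Hmgcr and Cyp51 were at 0.55, 0.46 and 0.39. Dhcr24 was at 0.28 without KO replicates 3 and 4, and without WT replicate 1 Cyp51 was at 0.68 and Cdkn1a at 1.42. Without KO replicate 2, the mean difference was 0.17 for immediate early genes (limma camera adjusted p = 0.260), 0.13 for inflammatory cytokines (0.661) and 0.20 for p53 targets (0.130). Without that library Zfp36, Dusp1, Ier3 and Egr1 were at 0.37, 0.33, 0.43 and 0.08, Lcn2, Ptgs2, Il11 and Lif at 1.39, 0.94, 0.59 and 0.40, Cdkn1a at 0.35 and Hmgcr at 0.18. The mean of the cytokines was 0.54 without WT replicate 2 (limma camera adjusted p = 0.053) and 1.40 without KO replicate 1. The fatty acid and cholesterol call was lost without WT replicate 2, with a mean of 0.21 (limma camera adjusted p = 0.0695), WT replicate 3, at 0.07 (0.457), KO replicate 1, at 0.18 (0.134), or KO replicates 3 and 4, at 0.06 (0.407). The mean was 0.35 without WT replicate 4 and 0.43 without KO replicate 2.

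Among lists of other cell types, macrophage genes had a mean log2 difference of -0.48 (SE 0.48, limma camera adjusted p = 0.000165, and adjusted p = 0.990 with an estimated correlation), and 15 of 18 members were lower in KO tumours. Mpeg1, Fcgr1, Adgre1 and Lyz2 had log2 fold changes of -0.86, -1.14, -1.01 and -0.91. Adgre1 was at -0.67 without WT replicate 2 and Lyz2 at -0.59 without KO replicate 1. The endothelium list had a mean difference of -0.25 (SE 0.37, limma camera adjusted p = 0.0434, and adjusted p = 0.990 with an estimated correlation), with Cldn5 at -0.73, Kdr at -0.69, Tek at -0.70 and Pecam1 at -0.40. Tek was at -0.46 without WT replicate 2 or WT replicate 4. Pecam1 was at -0.24 without KO replicates 3 and 4, -0.27 without WT replicate 4 and -0.63 without KO replicate 2. The adipocyte list was called on the higher side (limma camera adjusted p = 0.0215, and adjusted p = 0.990 with an estimated correlation) with a mean difference of 1.66 (SE 1.93). Its mean log2 CPM was 0.08, 0.14, 0.13 and 5.42 in WT replicates 1 to 4. In KO replicates 1, 2 and the summed 3 and 4 it was 4.15, 0.32 and 4.85. The difference thus reflects which samples held adipocyte transcripts at a high level. By edgeR log2 fold change, a scale unlike that of the mean, its median member was at -0.03. Fabp4, Pck1, Cidea and Lipe were at -1.60, 2.62, -1.70 and 0.26. Without WT replicate 1, Fabp4 was at -0.18 and Cidea at 1.09, and Lipe ran from -0.09 without KO replicates 3 and 4 to 0.61 without WT replicate 4. Without KO replicate 1, the mean difference was -0.13 for macrophage (limma camera adjusted p = 0.361), -0.10 for endothelium (0.573) and 1.08 for adipocyte (0.364). Without KO replicate 2 it was -0.91, -0.52 and 2.91. The endothelium call was also lost without WT replicate 1, with a mean of -0.16 (limma camera adjusted p = 0.257), WT replicate 2, at -0.22 (0.0651), WT replicate 4, at -0.09 (0.452), or KO replicates 3 and 4, at -0.12 (0.555). Its mean was -0.47 without WT replicate 3. The adipocyte call was also lost without WT replicate 2, with a mean of 1.24 (limma camera adjusted p = 0.148), WT replicate 3, at 1.24 (0.401), or KO replicates 3 and 4, at 0.77 (0.473).

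In all, 9 of the 34 lists tested were called by limma camera with the preset correlation, 7 higher and 2 lower in KO, and 0 by camera with an estimated correlation or by fry. The adjusted p of 0.990 with an estimated correlation was shared by every list, because the adjustment gave them all one value. Unadjusted, camera with an estimated correlation gave the called lists p from 0.0698 for p53 targets to 0.394 for endothelium. Exact permutation of the list means also called 0, but its smallest p of 0.0286 passes the adjustment only if most of the lists reach it together. That count therefore says little. Unadjusted, the exact permutation p of the called lists ran from 0.143 for p53 targets to 0.60 for luminal urothelium, so none was under 0.05. Over the members of all lists, 0 genes passed the edgeR test over all genes, and 1 passed when adjusted over the list alone, Gdf15 among the p53 targets. Each of the other 34 splits of the 7 samples into 4 and 3 called 9 to 23 lists, so the number called was no larger than chance splits gave. Left-out libraries moved it from 6 lists without KO replicate 1 to 17 without WT replicate 1, and it was 14 without WT replicate 3 and 14 without KO replicate 2.

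**Figure D3:**
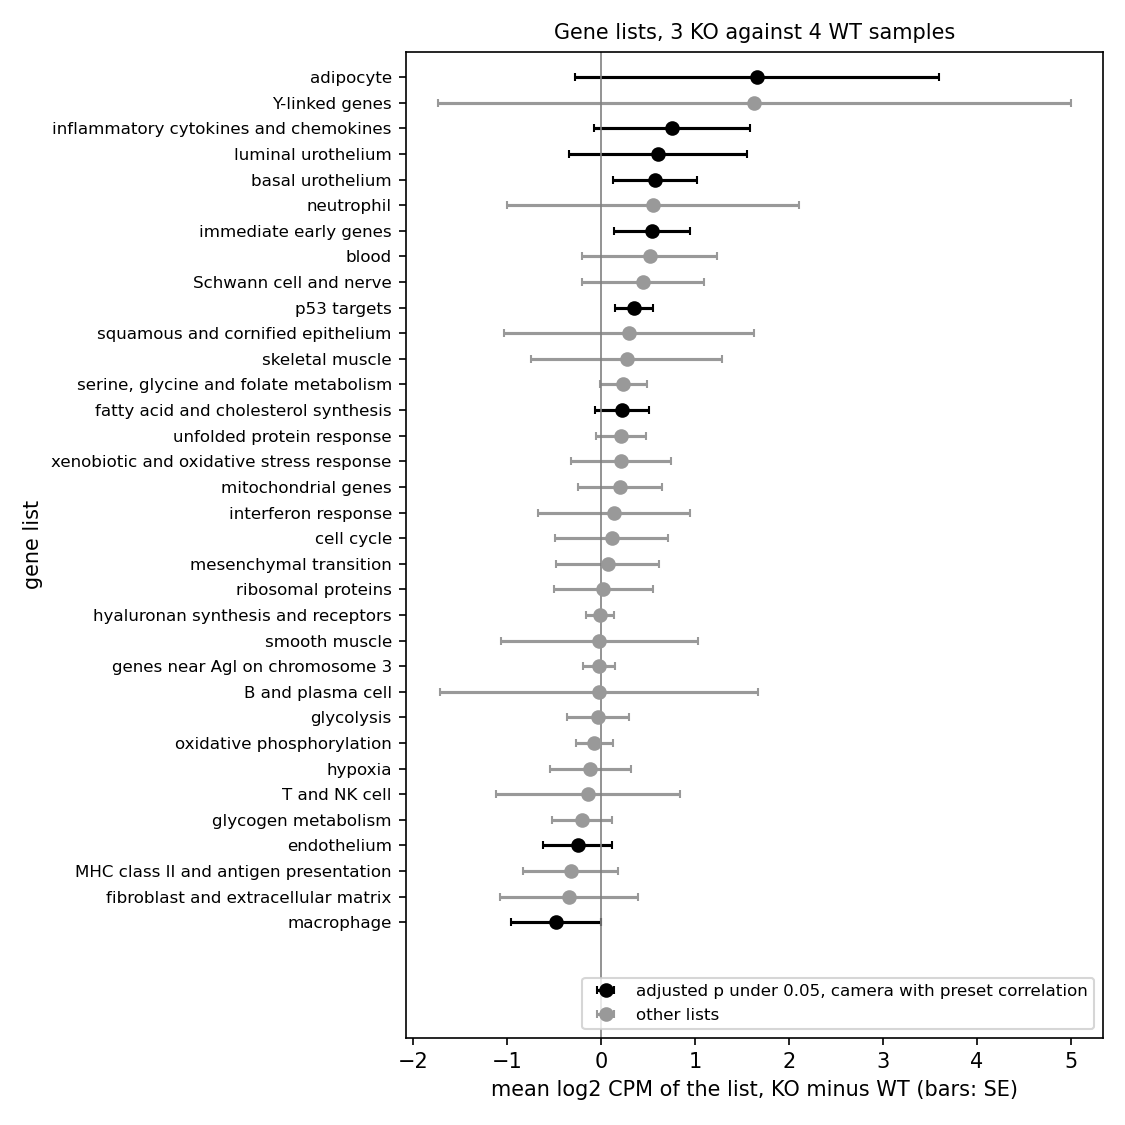
Difference in mean log2 CPM between KO and WT tumours (horizontal axis) for the 34 gene lists tested, with bars for the standard error over 3 KO and 4 WT samples. Black points mark the 9 lists called by limma camera with the preset correlation, from macrophage at -0.48 to adipocyte at 1.66, and none was called with an estimated correlation.

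The remaining lists did not pass limma camera's test with all 7 samples, although 21 of the 25 lists not called passed in at least 1 fit with a sample left out. On its higher side, the mean log2 differences were 0.45 for Schwann cell and nerve, 0.52 for blood, 0.20 for mitochondrial genes, 0.55 for neutrophil, 0.22 for the unfolded protein response, 1.63 for Y-linked genes, 0.21 for the xenobiotic and oxidative stress response, 0.12 for cell cycle, 0.30 for squamous and cornified epithelium, 0.14 for the interferon response, 0.02 for ribosomal proteins, -0.03 for glycolysis, 0.28 for skeletal muscle and 0.07 for mesenchymal transition. On its lower side they were -0.34 for fibroblast and extracellular matrix, -0.32 for MHC class II and antigen presentation, -0.07 for oxidative phosphorylation, -0.11 for hypoxia, -0.14 for T and NK cell, -0.02 for smooth muscle, -0.02 for genes near Agl on chromosome 3 and -0.02 for B and plasma cell. In the B and plasma cell list the median member was at -0.93 and 0 of 14 members lay above 0, and in smooth muscle the median was -0.70 with 0 of 20 above 0. The median member had the other sign than the mean in neutrophil (-0.07), cell cycle (-0.09), squamous epithelium (-0.97), ribosomal proteins (-0.12) and skeletal muscle (-0.50), and in glycolysis the mean and the median (-0.17) both differed from the sign of the test. These medians and member counts are of edgeR log2 fold changes, which follow mean counts, while the means are of log2 CPM. The scale alone can therefore make the signs differ. The list of male accessory glands had 2 tested members and was not tested.

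Landmark genes of the tumour tissue differed between the group means by less than the SD of the WT samples. Krt5, a basal keratin, was at 6187 ± 798 CPM in KO (SD, n = 3) and 4875 ± 1601 in WT (SD, n = 4), and Krt14 at 5812 ± 1362 and 5995 ± 6667. Upk2, a uroplakin of umbrella cells, spanned 10.8 to 310.4 CPM over KO and 1.24 to 340.4 over WT samples. The muscle myosin gene Myh11 spanned 464 to 1606 CPM in KO and 47.2 to 4967 in WT, and the collagen gene Col1a1 spanned 572 to 3159 and 291 to 3263. Log2 fold changes of Trp63 and Mki67 were -0.14 and -0.41. Trp63 ran from -0.39 without KO replicates 3 and 4 to 0.11 without KO replicate 2. Mki67 rested on single libraries, at -0.01 without WT replicate 1 and -0.73 without WT replicate 4. Samples of one genotype were no more alike than samples of different genotypes, with a mean Spearman correlation of 0.905 within and 0.921 between groups, a difference of -0.016 (exact permutation over 35 splits, one-sided, p = 1).

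Sex is not given in the labels, and the sex-linked genes differed between samples of each group. Xist, the RNA that coats the inactive X chromosome, was at 1350 CPM in WT replicate 3, at 457 in WT replicate 4 and at 1251 in the summed KO replicates 3 and 4. It was at 0.276 CPM in WT replicate 2, 0.181 in KO replicate 1 and 0.507 in KO replicate 2, where the Y-linked gene Ddx3y was at 48.7, 41.4 and 69.3 CPM. WT replicate 1 held both, with Xist at 105 and Ddx3y at 7.08 CPM.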

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

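The splits of the samples and the test on antibody genes were set out before their results were seen. Chosen only after the result was seen were the tests of 2 mice with similar tumours for KO replicates 3 and 4, on Xist and Y-linked genes in WT replicate 1 and on Agl in KO replicate 2.

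The libraries of KO replicates 3 and 4 were nearly equal in every part of the profile. The chi-square per degree of freedom was 1.81 between them, against at least 63.9 in the other 27 pairs. Counts of immunoglobulin variable genes, whose use was taken to differ between animals, had a Spearman correlation of 0.951 between these libraries over 127 genes. The other 27 pairs reached at most 0.520. This fits 2 libraries made from 1 RNA sample and argues against 2 mice with similar tumours. The antibody genes cannot tell 1 RNA sample from 2 preparations of 1 mouse, and the chi-square of 1.81 is above the value of 1 from counting error alone. Whether RNA was sequenced again on purpose, a tube was taken again or 1 mouse gave 2 preparations stays open. The design names no biological explanation to test, since both libraries have the same labels.

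WT replicate 1 held both Xist (105 CPM) and Y-linked reads. A single mixture of male and female material would bring the Y-linked genes to one share of their mean in the 3 samples with a male pattern. Kdm5d was at 89.2%, Eif2s3y at 64.9%, Ddx3y at 13.3% and Uty at 11.9%, a highest-to-lowest ratio of 7.47 against at most 2.49 in those 3 samples. Those samples are part of the mean they are measured against, which lowers their ratios. In KO replicate 2, Eif2s3y was at 76.9 CPM against 33.4 in WT replicate 2 and 34.5 in KO replicate 1. Uty was at 8.87 there, against 17.4 and 15.2. The comparison therefore cannot decide on a mixture. Reads carried over from a library with high Xist are argued against, since for each of the 3 candidate libraries at least 37 abundant genes were too low for the share needed. A mixture stays open, as do differences in Y-linked expression between the cell types of a mixed sample. No biological explanation was tested, since the labels give no sex.

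Agl in KO replicate 2 was at 35.2% of the WT mean, above the other KO samples. Reads carried over from a WT library of the series would have to make up 15.4% to 38.7% of it, and at least 97 abundant genes were too low for such a share from any of the 4 WT libraries, which argues against this source. A knockout that leaves some transcript, or WT cells from a mouse outside the series, stays open. The genotype named by the design was not tested against either, as the labels do not say which part of Agl was removed.

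Dixon's test at the 95% level set 1 WT sample apart in 15 of 200 genes and lists tested, where chance sets about 1 in 20 groups apart, here 10. The gap to the nearest sample, as a share of the range, is given for log2(CPM + 1) of genes. WT replicate 1 stood apart in Hmgcr (0.862), Cidea (0.912), Ifit2 (0.853), H2-Aa (0.906) and H2-Ab1 (0.849). WT replicate 2 stood apart in Ppp1r3b (0.882). WT replicate 3 stood apart in Retnlg (0.918), mt-Atp6 (0.832), Has3 (0.884) and the mean of the fibroblast and extracellular matrix list (0.902). WT replicate 4 stood apart in Mthfd1 (0.844), Ndufa9 (0.851), Pck1 (0.958), Atf3 (0.96) and the mean of the adipocyte list (0.988).

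For the genes called by edgeR, the count over splits says nothing about chance: the real split called 0 (337 at an unadjusted p under 0.05; DESeq2 called 5, or 2 on the genes kept by edgeR's filter, and limma voom 0), so all 35 splits had to reach it, and the highest of the others called 3. Chance cannot be excluded for the other counts of the comparison. At an unadjusted p under 0.05, 30 of the 35 splits gave at least its 337 genes, and the highest was 3294, for WT replicates 1 and 3 with KO replicate 2 against the rest. All 35 splits called at least its 9 lists, and the highest of the others was 23. That highest count of genes, several times the real one, is the largest picked from all the other splits, so alone it is no evidence of a particular structure. Its samples were, however, the lowest on the leading principal component described below: WT replicate 1 at -129, WT replicate 3 at -9.30 and KO replicate 2 at -50.3. The next highest count, 2904, was for WT replicates 2 and 4 with KO replicate 1, the highest on it at 51.2, 81.4 and 40.5. This overlap with the component was seen afterwards and was not tested.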

How the results depend on the processing

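Chosen only after the data were seen were the DESeq2 test on the genes kept by edgeR's filter, the fits with KO replicates 3 and 4 apart, without both of them, without WT replicate 1 and KO replicate 2, and with a Y-linked or smooth muscle covariate. Agl stayed below 0 in all 26 alternative fits, from -3.69 without WT replicate 1 and KO replicate 2 to -2.14 without KO replicate 1, and its adjusted p was smallest, at 0.0906, with DESeq2 on the genes kept by edgeR's filter, or 0.169 with DESeq2's own. Genes changed between KO and WT came to 5 with DESeq2 and its own filter (24387 genes tested), to 2 with DESeq2 on the genes kept by edgeR's filter (15411 tested) and to 0 in the other 25 alternatives by edgeR and limma, with 206 to 1252 genes at an unadjusted p under 0.05; left-out replicates gave a range of 0 to 0. The edgeR test with no filter (24695 tested) called 0, so the filter alone gave no calls in edgeR. The DESeq2 fits differed both in the genes kept and in the use of DESeq2's own filter, so their difference cannot be put down to either. Gene lists changed between KO and WT came to 0 with an estimated correlation, 0 with fry, which both take account of correlated members, to 0 with exact permutation of list means, whose smallest p nearly rules out a call over 34 lists, and to 6 to 17 when replicates were left out. The basal urothelium list was called in all 19 alternatives with camera and the preset correlation, macrophage and p53 targets in 18, immediate early and luminal urothelium in 17, inflammatory cytokines in 16, fatty acid and cholesterol synthesis in 15, and adipocyte and endothelium in 12. No called list changed direction in its test, though the mean difference of luminal urothelium turned from 0.61 to -0.03 without WT replicate 1, and with no filter the male accessory gland list was called too. Of the 25 lists not called, 21 passed camera in at least 1 alternative, 41 of these 52 calls with a sample left out. Fibroblast and extracellular matrix passed in 6 alternatives, ribosomal proteins in 5, interferon response and Schwann cell and nerve in 4, and cell cycle, smooth muscle and squamous epithelium in 3. In 8 calls, over 6 lists, the direction was opposite to that with all samples: ribosomal proteins (-0.17 without WT replicate 2, -0.17 without WT replicate 4, -0.27 without KO replicate 2), interferon response (-0.39 without WT replicate 1), smooth muscle (0.61 without WT replicate 2), cell cycle (-0.33 without WT replicate 4), mesenchymal transition (-0.43 without KO replicate 2) and B and plasma cell (0.73 with the Y-linked covariate). The difference in similarity within and between groups stayed below 0 in 15 alternatives, from -0.129 to -0.006, and none passed. No paired analysis was possible because the replicate numbers follow the order of the samples and the labels share none between groups. A count of 0 allows up to 3 reads, little beside at least 15919607 reads per library, while at the spread of these tumours 22% of simulated 4-fold changes were recovered.

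Of the 20 genes named by p, which were chosen for their separation in these samples, Cyp2a5 (3.05), Wnt3a (1.97) and Gdf15 (2.07) passed with DESeq2 and its own filter, and Cyp2a5 (3.05) alone on the genes kept by edgeR's filter. Other named genes, none of them past the threshold, did change sign, some from values well away from 0 such as Cidea (-1.70), Fabp4 (-1.60), Egr1 (1.12), Myh11 (-1.02) and Has2 (-0.60), and the cause was not tested. Cidea and Fabp4 were at 18.8 and 1451 CPM in WT replicate 1, against at most 0.986 and 374 in the other WT samples. Egr1 was at 398 CPM in KO replicate 2, against at most 118 in the other samples. Under upper-quartile factors and library totals Shmt1 was at -0.017 and -0.0047. With limma voom, Shmt2, Upk2, Krt14, Myh11 and Col1a1 were at 0.23, 0.70, 0.55, 0.35 and 0.040. With sample quality weights, Hmmr, Mki67, Cidea, Has2, Shmt2, Xist, Krt14 and Trp63 were at 0.24, 0.17, 0.67, 0.96, 0.40, 2.76, 1.03 and 0.13. On log2(FPKM + 1), Shmt1, Shmt2, Upk2, Krt14 and Myh11 were at -0.0078, 0.16, 0.58, 0.51 and 0.20, and on log2(FPKM + 0.1) at -0.0080, 0.17, 0.74, 0.52 and 0.24. With KO replicates 3 and 4 apart, Shmt1 and Xist were at -0.041 and 0.38. Without WT replicate 1 and KO replicate 2, Fabp4, Cidea, Egr1, Has1, Has2, Shmt2, Xist, Krt14 and Trp63 were at 0.12, 1.16, -0.035, 0.30, 0.28, 0.70, 0.053, 0.94 and 0.25. With the Y-linked covariate, Shmt1 and Krt14 were at -0.051 and 0.0087. With the smooth muscle covariate, Shmt2, Upk2, Krt14, Myh11 and Col1a1 were at 0.12, 1.44, 0.39, 0.40 and 0.040. The hyaluronan list, on the higher side in camera, was on the lower side with a mean difference of -0.0082 by exact permutation, -0.079 with no filter and -0.18 without WT replicate 1 and KO replicate 2. With replicates left out in turn, the lowest and highest values were -0.91 and 0.077 for Hmmr, -2.06 and 1.09 for Cidea, -0.086 and 0.61 for Lipe, -0.53 and 0.27 for Has1, -1.64 and 0.0012 for Has2, -0.23 and 0.42 for Has3, -0.12 and 0.23 for Shmt1, -0.36 and 0.75 for Shmt2, -10.4 and 1.16 for Xist, -2.09 and 0.64 for Upk2, -0.38 and 1.10 for Krt14, -0.39 and 0.11 for Trp63, -1.26 and 0.71 for Col1a1, -0.38 and 0.026 for the glycogen list and -0.11 and 0.098 for the hyaluronan list. Of the 25 lists that were not called, 23 changed direction in at least 1 alternative.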

Other observations

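The test in this part was chosen only after the result was seen.

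Expression of the smooth muscle list differed widely between tumours. The mean log2 CPM of the smooth muscle list was 5.31, 9.68, 7.09 and 9.40 in WT replicates 1 to 4, and 8.26, 7.66 and 7.64 in KO replicates 1, 2 and the summed 3 and 4. All 20 members had an edgeR log2 fold change below 0, with a median of -0.70, although the mean of their log2 CPM differed by -0.02, since WT replicates 2 and 4 set the WT mean CPM. Squamous and cornified epithelium went the other way in WT, at 9.06, 4.59, 5.93 and 4.28, and stood at 6.39, 4.89 and 7.52 in KO tumours. B and plasma cell genes were at -1.79, -0.07, 3.75 and 3.64 in WT and at 1.77, -0.51 and 2.81 in KO tumours.

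The leading principal component of the 7 samples held 42.2% of the variance and did not follow genotype. A candidate explanation is the share of bladder wall muscle in each piece of tissue. Computed without the smooth muscle genes, the component correlated with the smooth muscle list mean at a Pearson r of 0.916 (exact permutation p = 0.00377) and a Spearman rho of 0.857 (exact permutation p = 0.0238) over n = 7 samples, and r was 0.815 without WT replicates 1 and 2, the samples farthest from the median. This was 1 relation, and no other correlation was computed. Some other lists had their extremes where the component of all genes did, at -129 in WT replicate 1 and 81.4 in WT replicate 4. Mean log2 CPM there was 0.648 and 3.31 for Schwann cell and nerve and, in reverse, 5.60 and 3.20 for cell cycle. The relation is therefore not shown to be particular to muscle. A common difference between tumours that moves muscle and other genes together would give the same correlation.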
